A study of Mus musculus with 4 samples.

How the data were processed

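The series measured histone H3 trimethylated at lysine 4 (H3K4me3), a modification that marks active and poised promoters, by chromatin immunoprecipitation and sequencing (ChIP-seq) of mouse hippocampus. The tissue came from adult male B6CASTF1/J mice of 2 months, a first-generation hybrid of a common laboratory strain and a wild-derived strain. There were 4 libraries. They were 2 technical replicates each of pool D (biological replicate 1) and pool C (biological replicate 2). Each pool combined 7 tissue samples, which the labels describe as layer of hippocampus. That label names no particular layer, and the tissue is called hippocampus below. Library fragments were in the size range 200 to 600, and the chromatin came from frozen tissue, per the labels.

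The authors deposited 4 peak lists on mouse genome build mm10. Per the labels, 1 list was called on pool D, 1 on pool C and 1 on both pools together, all as pseudoreplicated peaks, and 1 list holds replicated peaks. The per-library notes name the alignment each list was derived from, and these notes were used to tell the pool D list from the pool C list. Both technical replicates of a pool share 1 alignment, so each pool gave 1 list and the technical replicates could not be compared. The notes also name a control alignment. The peak caller, its version and its settings are not given in the sources used here. Each peak has a signal value, which the authors deposited as the enrichment of the peak on a scale set by their caller. It was used only to rank or filter peaks within 1 list. Each peak also has a −log10 p and a −log10 q value as deposited by the authors. The lists reach down to weak peaks, with a lowest −log10 q of 0.26 in the replicated list, where 357 peaks (1.32%) had q above 0.05. Sequencing depth is unknown from the files used here, so no counting interval could be given, and unequal depth between the pools would change how many weak peaks each list holds.

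The replicated list was the main list. Coordinates were set against the mouse assembly GRCm38, the same build as mm10, and the GENCODE gene annotation release M21. All peaks lay within the lengths of the 21 chromosomes of that assembly. A promoter was the window of 1 kb on either side of any transcription start site (TSS) of a protein-coding transcript, over 21853 protein-coding genes with 54361 start sites. A gene carried the mark if a peak shared at least 1 bp with such a window. This rule can assign a peak of a neighbouring promoter to a gene, and such neighbours are named where they matter. A promoter domain was formed by joining peaks within 1 kb of each other, and its breadth is its length in bp. A gene with several domains was given its broadest.

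Overlap between the single-pool lists was the share of peaks with at least 1 bp in common and the Jaccard index of covered bases. Each was compared with 100 circular shifts of peaks along their chromosomes, for which the smallest possible permutation p is 0.0099. The share of each of 26 gene lists with a promoter peak was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 26 lists. Domain breadth was compared by a two-sided permutation test of the list median, with 100000 draws of genes with a peak and adjustment over the 19 lists with at least 5 marked members. The smallest p those draws can give is 2e-05. Genes are not independent replicates, and these p-values describe the peak lists, not differences among animals. Values per pool are given as mean ± SD over the 2 pools. GC content and CpG content were taken from 500 bp on either side of the gene's 5′ end, which is not always the start site that carried the mark.

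The gene lists cover housekeeping genes, neurons in general, excitatory neurons, hippocampal fields, interneurons, astrocytes, oligodendrocytes, their precursors, microglia, endothelium, mural and meningeal cells, and ependyma with choroid plexus. The others are immediate early genes, vesicle release, voltage-gated channels, H3K4 methylation enzymes and readers, Hox genes, factors of other lineages, liver, striated muscle, pluripotent and germ cells, lymphoid and erythroid cells, keratinocytes, olfactory receptors, vomeronasal receptors and imprinted genes. Of 580 list entries, 6 names had no protein-coding gene in the annotation. The lists, the tests and the rule for naming genes were fixed before the data were examined. That rule took the 20 broadest promoter domains with 1 gene each, the gene with the start site nearest the summit of the strongest peak. It took from each list the 2 members with the broadest domain and the first 2 by symbol without a peak. It also took the 5 strongest peaks over 10 kb from any start site, and the 5 broadest promoter domains found in 1 pool alone. A few genes that this rule takes are not reported here.

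The alternatives were a stricter threshold of −log10 q of at least 5, each single-pool list or the list on both pools together in place of the replicated list, reciprocal overlap of 50%, and lists of equal length. Promoter windows of 500 bp and 2.5 kb, start sites of all gene types, the gene's 5′ end alone, gaps of 0 bp and 3 kb within a domain, and covered bases within 5 kb of the start site were also tried. A threshold of −log10 q of at least 2 was chosen after seeing the data, as was the comparison of domain breadth between pools by gene list with its settings.

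The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data. With 24690 peaks, planted overlaps were found in 100% of cases and randomly placed peaks overlapped in 2.85%. The planted peaks were moved by less than the width of the narrowest peak, so the first value was certain and only checks the calculation. Among 21853 genes, simulated lists with a share of 95 percent were called in 90.2% of cases, lists with a share of 20 percent in 98.2% and unchanged lists in 1.33%. Among 14169 genes, lists made 1.5 times broader were called in 77.0% of cases, lists made 2 times broader in 99.0% and unchanged lists in 1.09%. The simulated breadth lists held 20 genes each, while the smallest list tested held 5 marked genes, and none was made narrower. These rates therefore do not cover smaller lists or calls of narrower domains.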

Results

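H3K4me3 was profiled in adult male mouse hippocampus from 2 pools of tissue, pool D and pool C, with 2 technical replicate libraries each. The replicated list held 27063 peaks on build mm10, which covered 41.5 Mb (1.52% of the genome) with a median width of 1203 bp. The pool D list held 24690 peaks over 35.0 Mb and the pool C list 34193 peaks over 48.0 Mb. The list called on both pools together held 31301 peaks, and 26600 of the replicated peaks (98.3%) recurred in it with identical ends. Of the replicated peaks, 84.2% overlapped a peak of the pool D list and 97.9% a peak of the pool C list. A replicated peak was therefore not always present in both single-pool lists. The labels name no second tissue or treatment. The comparisons are therefore how far the pools agree, where the mark lies, and which groups of genes carry it and how broadly.

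Nearly every pool D peak was also found in pool C, while 11863 pool C peaks, mostly weak and away from promoters, had no pool D counterpart. Of the 24690 pool D peaks, 24520 (99.3%) shared at least 1 bp with a pool C peak, against at most 3.98% in 100 shifted lists (permutation p = 0.0099, the smallest the shifts allow). Of the 34193 pool C peaks, 22330 (65.3%) met a pool D peak, against at most 2.88% in shifted lists (permutation p = 0.0099). The Jaccard index of covered bases was 0.718, and no shifted list exceeded 0.00969. The difference lay in the weak peaks. In the lowest decile of signal value of the pool C list 4.91% of peaks were found in pool D, in the fifth decile 81.7%, and from the seventh decile upward 100%. In the pool D list 94.9% of the lowest decile were found in pool C. With reciprocal overlap of 50% required, the lowest deciles fell to 42.8% in pool D and 2.40% in pool C. Of the 11863 pool C peaks without a pool D peak, 47.6% lay in introns, 24.9% were intergenic and 11.9% lay at protein-coding promoters, against 66.5% at promoters among pool C peaks that overlapped pool D.

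**Figure D1:**
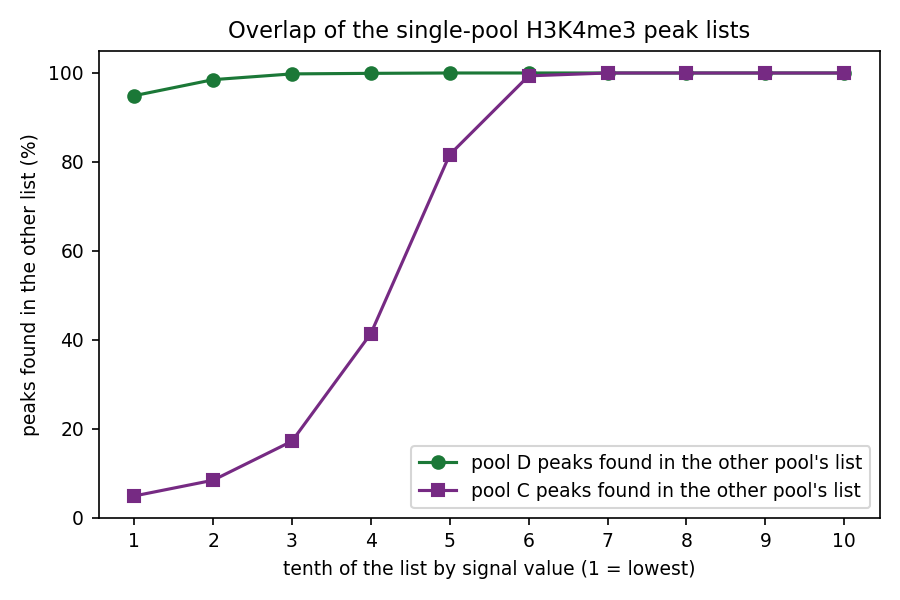
Percentage of peaks found in the other pool's list (y axis) by decile of signal value within each list (x axis, 1 is the lowest), for pool D (circles) and pool C (squares). In pool D the share was 94.9% in the lowest decile, whereas in pool C it was 4.91% in the lowest and 100% from the seventh decile.

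In the replicated list most peaks lay at promoters of protein-coding genes, and 14169 of 21853 such genes (64.8%) carried the mark. Of the 27063 replicated peaks, 15515 (57.3%) reached a protein-coding promoter, against a mean of 4.25% and a maximum of 4.85% in shifted lists (permutation p = 0.0099). A further 2130 peaks (7.87%) lay only at promoters of other gene types, 779 (2.88%) in exons, 4671 (17.3%) in introns and 3968 (14.7%) between genes. The share at protein-coding promoters was 62.7% in the pool D list, 47.6% in the pool C list and 51.3% in the list on both pools together. In the replicated list promoter peaks had a median width of 1872 bp, and the 4540 peaks over 10 kb from any start site one of 557 bp. Promoters of 13907 genes carried a peak in both pools, those of 572 genes in pool C only and those of 4 genes in pool D only. Genes with a promoter peak had a median GC content of 58.6% around the gene's 5′ end and 60 CpG dinucleotides, and genes without one 45.6% and 9. The ratio of observed to expected CpG was 0.710 and 0.173 (permutation p = 1e-05 for GC content and for the ratio, the smallest the draws allow).

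Chromosome X carried fewer peaks than the autosomes. It had 4.48 peaks per Mb and the autosomes 10.7, and 50.4% of X-linked protein-coding genes had a promoter peak against 66.1% of autosomal genes. The mice were male, and the copy number of X was not allowed for in either comparison. Gene density was not allowed for in the peaks per Mb. A lower marking of X-linked promoters as such was therefore not tested. On chromosome Y the marked genes were Ddx3y, Eif2s3y, Kdm5d and Uty, with domains of 2229, 1761, 1523 and 1959 bp. Xist, the noncoding RNA of the inactive X chromosome, had no promoter peak in the replicated list or either pool. These 5 genes were chosen after their values were seen.

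Genes of neurons and astrocytes were marked almost throughout. All 26 genes of neurons in general, all 21 of excitatory neurons, all 24 of the vesicle release machinery, all 25 voltage-gated channel genes and all 25 immediate early genes, which respond to neuronal activity within minutes, had a promoter peak in the replicated list and in both pools. So did all 20 astrocyte genes, all 25 housekeeping genes and all 22 H3K4 methylation enzymes and readers. Each of these lists was marked more often than other genes, of which about 64.8% carried a peak (Fisher's exact test, adjusted p between 4.39e-05 and 0.000343). Housekeeping and vesicle release genes were, however, within the range of genes matched on CpG count (80% to 100% and 79.2% to 100% of draws), and the other lists of this group lay above theirs. Of the hippocampal field genes 23 of 25 were marked (Fisher's exact adjusted p = 0.00391), among them Prox1, a transcription factor of dentate granule cells, while Iyd and Lct had no peak in either pool. Of the imprinted genes 21 of 23 were marked (Fisher's exact adjusted p = 0.00949), with Dlk1 and Ndn the exceptions. Dlk1 had a domain of 430 bp in pool C alone. With only the gene's 5′ end as start site the imprinted list was marked at 73.9% and no longer stood apart (Fisher's exact adjusted p = 0.287).

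Interneuron and oligodendrocyte lineage genes were also marked more often than other genes, with more of them in pool C than in pool D. Of 25 interneuron genes 22 (88.0%) were marked (Fisher's exact adjusted p = 0.0224), 19 in pool D and 23 in pool C, and genes matched on CpG count ranged from 64.0% to 88.0%. Gad1, which makes GABA, and Maf had the broadest domains, and Nkx2-1 and Sst, which encodes somatostatin, had no peak in the replicated list. Sst had a domain of 256 bp in pool C. All 21 oligodendrocyte genes were marked (Fisher's exact adjusted p = 0.000226), 19 in pool D and 21 in pool C. Of 14 precursor genes 13 were marked (Fisher's exact adjusted p = 0.0296), 12 in pool D and 13 in pool C, and Neu4 had no peak. In the pool D list alone the interneuron share of 76.0% no longer stood apart, nor did its share with only the gene's 5′ end as start site (Fisher's exact adjusted p = 0.248 and 0.0819). The precursor call ended in either pool alone (adjusted p = 0.119 in pool D and 0.0502 in pool C, Fisher's exact test), at a −log10 q of at least 5, in the 500 bp window and at the 5′ end alone (0.119, 0.173 and 0.114), and the oligodendrocyte share fell to 61.9% among peaks with a −log10 q of at least 5 (Fisher's exact adjusted p = 0.825).

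In the replicated list microglia, vascular and ependymal genes were marked less completely, although endothelial genes (85.7%) came close to interneuron genes (88.0%). Endothelial genes lay above the range of genes matched on CpG count (47.6% to 76.2%). Mural and meningeal genes reached the upper bound of theirs (45% to 80%). Microglia and ependymal genes lay within theirs (24% to 56% and 38.9% to 72.2%). In pool C the endothelial share (95.2%) exceeded that of interneurons (92.0%), and the lists were not tested against each other. The pools differed most at microglia and endothelial genes. Of 25 microglia genes 10 (40.0%) were marked in the replicated list, fewer than among other genes (Fisher's exact adjusted p = 0.0145). The pool D list marked 6 of them and the pool C list 19, so that in pool C alone the share was 76.0% and did not differ from other genes (Fisher's exact adjusted p = 0.399). Sall1, a microglial transcription factor, carried the broadest domain. Aif1 and C1qa, a complement subunit, had no replicated peak, and domains of 369 and 323 bp in pool C alone. Of 21 endothelial genes 18 were marked, 15 in pool D and 20 in pool C (Fisher's exact adjusted p = 0.0697). The endothelial list stood above other genes in pool C alone (95.2%), in the list on both pools together (95.2%) and with promoter windows of 500 bp (85.7%) and 2.5 kb (90.5%; Fisher's exact adjusted p = 0.00537, 0.00334, 0.0469 and 0.0218). Foxq1 and Ly6c1 had no replicated peak. Of 20 mural and meningeal genes 16 were marked, 15 in pool D and 17 in pool C, with collagen gene Col3a1 and Lum unmarked (Fisher's exact adjusted p = 0.240). Of 18 ependymal and choroid plexus genes 9 were marked, 9 in pool D and 10 in pool C, and water channel gene Aqp1 and Ccdc153 were not (Fisher's exact adjusted p = 0.227).

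**Figure D2:**
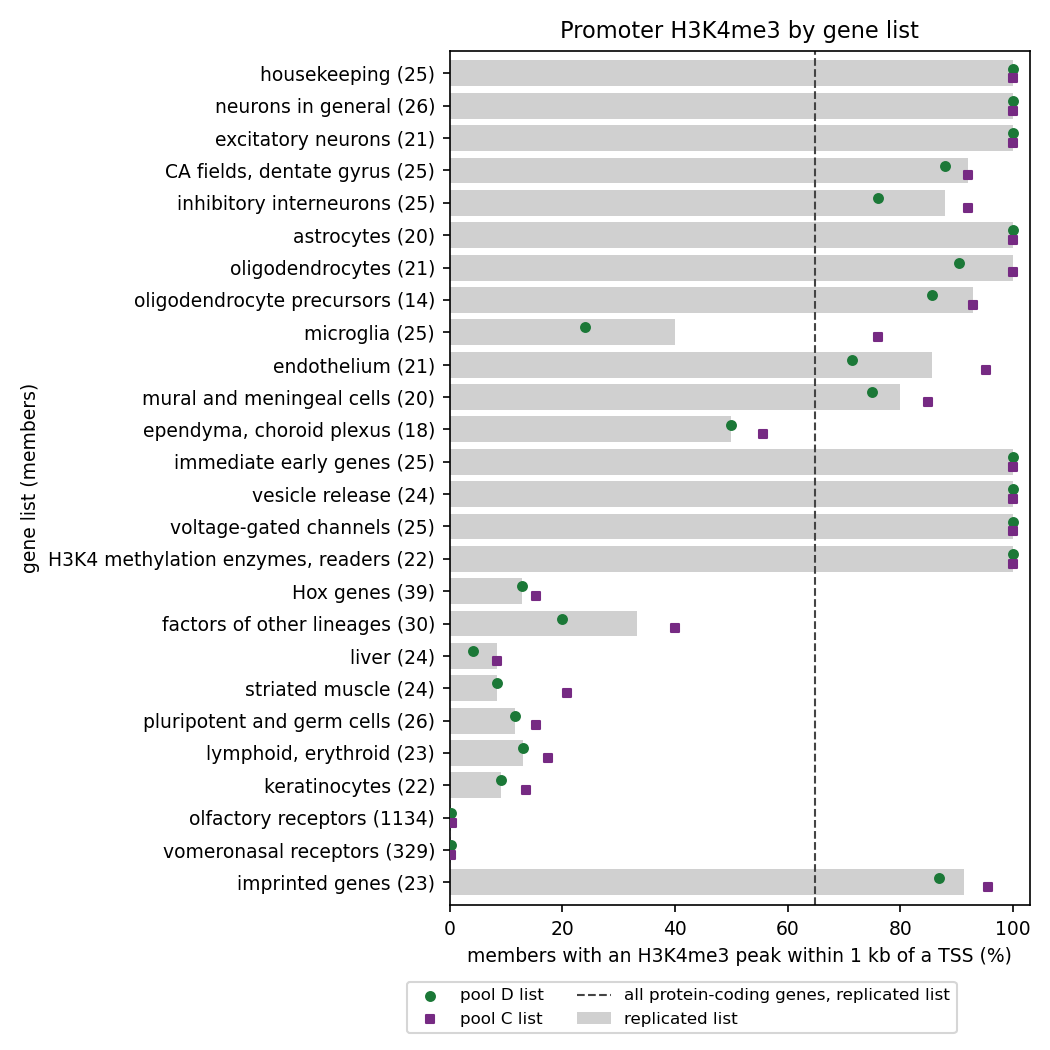
Percentage of the members of each gene list with an H3K4me3 peak within 1 kb of a start site (x axis), by list with its number of members (y axis). Bars show the replicated list, circles pool D and squares pool C, and the dashed line marks the 64.8% of all protein-coding genes. Microglia genes differ most between the pools, at 24.0% in pool D and 76.0% in pool C.

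Genes of other tissues and of the body axis mostly lacked the mark. Of 39 Hox genes 5 had a promoter peak (Fisher's exact adjusted p = 2.19e-10). The broadest were at Hoxd1 (1035 bp) and Hoxa7 (779 bp), and Hoxa10 and Hoxa11 had none. Of 30 transcription factors of other lineages 10 were marked (Fisher's exact adjusted p = 0.00110), 6 in pool D and 12 in pool C, including Gata2 and Sox17 and excluding intestinal factors Cdx1 and Cdx2. Of the 24 liver genes 2 were marked, as were 2 of 24 striated muscle genes, 3 of 26 genes of pluripotent and germ cells, 3 of 23 lymphoid and erythroid genes and 2 of 22 keratinocyte genes (Fisher's exact adjusted p between 6.41e-08 and 1.4e-06). The counts in pool D and pool C were 1 and 2 for liver, 2 and 5 for muscle, 3 and 4 for pluripotent and germ cells, 3 and 4 for lymphoid and erythroid cells, and 2 and 3 for keratinocytes. The genes without a peak included Ahsg and Alb of liver, Acta1 and Actc1 of muscle, Ddx4 and Dppa2 of germ and pluripotent cells, Alas2 of red cells, and Dsc1 and Dsc3 of skin. Dsc3 had a domain of 367 bp in pool C. Olfactory receptors were marked at 2 of 1134 genes, Olfr94 and Olfr750, with 2 in pool D and 5 in pool C, and vomeronasal receptors at 1 of 329, Vmn1r4 (Fisher's exact adjusted p = 3.63e-148 for the latter). Olfr1, Olfr10, Vmn1r1 and Vmn1r10 had none.

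Some of the marked members of these lists shared a domain with another gene. The domain of muscle gene Mylpf also held a start site of Tbc1d10b, that of Myl3 one of Pth1r, that of germ cell gene Tex14 one of Rad51c and that of Vmn1r4 one of Nt5c3. Domains with no other protein-coding start site were found at liver genes Apoa1 (988 bp, with no peak in pool D) and Apob (381 bp), at Esrrb (1819 bp), at Epor (2319 bp) and Klf1 (1417 bp) of the red cell lineage, and at Lor (2031 bp) and Krt10 (1829 bp) of skin.

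The 20 broadest promoter domains included those of transcription factor genes, of genes of neuronal signalling and of genes in neither group, a grouping made after the genes were seen and not tested. Nfib, a nuclear factor I gene, had the broadest at 22643 bp (chromosome 4, 82493299 to 82515941; 22686 ± 2823 bp over the pools, SD, n = 2). Other broad domains were those of Pou3f3 at 21737 bp (chromosome 1, 42683946 to 42705682; 18608.5 ± 5143 bp over the pools, SD, n = 2) and Nfia at 19240 bp (chromosome 4, 97771351 to 97790590; 19227 ± 163 bp, SD, n = 2). Further transcription factor genes among the 20 broadest were Nr2f2 (17900 bp), Zeb2 (17008 bp), Bcl11b (16764 bp), Prox1 (15493 bp), Zbtb20 (14824 bp), Myt1l (13663 bp) and Emx2 (13059 bp). Genes of neuronal signalling were the ephrin receptors Epha4 (16579 bp) and Epha7 (13616 bp), the NMDA receptor subunit Grin2b (15960 bp), the calcineurin subunit Ppp3ca (13823 bp) and the kinase Camk2a (13527 bp). Khdrbs3 (14931 bp) and Qk (14719 bp), which encode RNA-binding proteins, and Schip1 (13605 bp) and Tnrc18 (13442 bp) were also among them. Pools differed by more than 1.5 times at some of these domains. Epha4 measured 7513 bp in pool D and 17232 bp in pool C, Emx2 7241 and 15417 bp, Khdrbs3 8365 and 16867 bp, and Ppp3ca 9230 and 16319 bp. At Nr2f2 (8357 bp in pool D and 12877 bp in pool C), Bcl11b (10341 and 13137 bp) and Zbtb20 (12261 and 11810 bp) the replicated domain was broader than in either pool alone. Nr2f2 thus also differed by more than 1.5 times between the pools. Breadth also depended on the gap closed between peaks, and with none closed only Zbtb20 (11889 bp), Myt1l (11298 bp), Epha7 (10929 bp) and Qk (9929 bp) of the genes named here stayed within 1.5 times. Pou3f3 then measured 5613 bp, Nfib 13323 bp, Nfia 10250 bp, Nr2f2 3567 bp, Zeb2 5749 bp, Prox1 4079 bp and Camk2a 3474 bp. Among peaks with a −log10 q of at least 5, Nr2f2 measured 8820 bp, Grin2b 9878 bp, Emx2 7883 bp and Schip1 7608 bp, and with gaps of 3 kb closed Camk2a measured 23364 bp.

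Across the 14169 marked genes the median breadth was 2234 bp with quartiles at 1632 and 3134 bp, and 983 genes (6.94%) had domains over 5 kb. Over the 13907 genes marked in both pools, breadth correlated between them across genes, which are not independent replicates (Pearson r = 0.915 on log2 breadth, Spearman rho = 0.923). Domains were wider in pool C for 96.8% of these genes, by a median of 0.23 on the log2 scale (1.17 times).

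Excitatory neuron genes had the broadest domains of any list tested, with a median of 7193 bp, 3.22 times that of all marked genes (permutation test, adjusted p = 7.6e-05). Their medians were 6160 bp in pool D and 7103 bp in pool C, led by Grin2b and Camk2a. At the same adjusted p, and thus also beyond all draws of the permutation test, stood immediate early genes (4820 bp), astrocyte genes (4577 bp), genes of neurons in general (4433 bp) and voltage-gated channels (4339 bp). Named members included Nr4a3 (7687 ± 453 bp over the pools, SD, n = 2) and Fosl2 (6932 ± 805 bp), the glutamine synthetase gene Glul (9004.5 ± 1289 bp) and glutamate transporter gene Slc1a3 (8552 ± 1697 bp). Nefm (6587 ± 1121 bp) and Syt1 (7890 ± 1093 bp) led the neurons in general, and potassium channel gene Kcnd2 (6543.5 ± 309 bp) was among the broadest of the channels. With no gap closed between peaks, however, Kcnd2 measured 2535 bp, below the channel median of 3253 bp in that setting. The Glul domain also held a start site of Teddm2.

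Smaller excesses were found for vesicle release genes (3482 bp, led by Syt1 and Rph3a) and hippocampal field genes (3466 bp, led by Prox1 and Zbtb20), each with an adjusted p of 0.00190 in the permutation test. Housekeeping genes had a median of 3284 bp (permutation test, adjusted p = 0.00367), with Ywhaz and Eif4a2 the broadest. Imprinted genes had a median of 3281 bp (permutation test, adjusted p = 0.00766), led by Zrsr1 and by Peg3, whose domain also held a start site of Usp29. Endothelial genes had a median of 3279.5 bp (permutation test, adjusted p = 0.0106), led by Egfl7 and by Slco1a4, which measured 697 bp in pool D and 6689 bp in pool C. With no gap closed between peaks the housekeeping, hippocampal field, imprinted and endothelial calls ended (permutation test, adjusted p = 0.0620, 0.133, 0.137 and 0.831). In pool D alone the endothelial and imprinted calls ended (permutation test, adjusted p = 0.251 and 0.0783), the endothelial call also ended at a −log10 q of at least 5 (2904 bp, adjusted p = 0.0783), and the imprinted call ended for covered bases within 5 kb (permutation test, adjusted p = 0.486).

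Marked members of 5 lists had narrower domains than other marked genes, namely Hox genes, factors of other lineages, microglia genes, ependymal and choroid plexus genes, and mural and meningeal genes. Medians were 757 bp at the 5 marked Hox genes (permutation test, adjusted p = 0.00350), 1192.5 bp at factors of other lineages (adjusted p = 0.00342) and 1227 bp at microglia genes (adjusted p = 0.00367). Ependymal and choroid plexus genes had 1278 bp (permutation test, adjusted p = 0.00923; Enpp2 and Msx1 the broadest), and mural and meningeal genes 1427 bp (adjusted p = 0.00367), with Foxc1 and Zic1 the broadest. The Zic1 domain also held a start site of Zic4. All 5 medians lay within draws of genes matched on signal value, at 717 to 2469 bp for Hox genes, 494 to 1315 bp for factors of other lineages, 634 to 1799 bp for microglia genes, 830 to 2265 bp for ependymal genes and 708 to 1464.5 bp for mural genes. The microglia median was 548 bp in pool C alone and the mural median 873 bp in pool D alone. In the pool D list alone the calls for microglia genes and factors of other lineages ended (permutation test, adjusted p = 0.118 and 0.517), and in pool C alone that for mural and meningeal genes (adjusted p = 0.0600). The microglia call also ended at a −log10 q of at least 5, in the list on both pools together and with gaps of 3 kb closed (permutation test, adjusted p = 0.528, 0.0706 and 0.501). No difference passed the permutation test for interneuron genes (2242 bp, adjusted p = 0.983), oligodendrocyte genes (2691 bp, adjusted p = 0.173), precursor genes (2114 bp, adjusted p = 0.780) or H3K4 methylation enzymes and readers (2842 bp, adjusted p = 0.0694; Setd1b and Kmt2a the broadest). In pool D alone the last of these was called broader (2688.5 bp, permutation test, adjusted p = 0.0330). Oligodendrocyte genes were called broader in pool C alone (3515 bp) and in the list on both pools together (3084 bp), and narrower with no gap closed (1461 bp; permutation test, adjusted p = 0.0110, 0.0287 and 0.00808). Against draws matched on signal value the oligodendrocyte, interneuron and precursor medians lay above the range (717 to 1454, 1031 to 1918.5 and 784 to 1950 bp), and that of the H3K4 list within it (2004.5 to 3104 bp). Precursor genes were called broader in pool C alone (3650 bp) and with gaps of 3 kb closed (4348 bp; permutation test, adjusted p = 0.0255 and 0.00503).

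**Figure D3:**
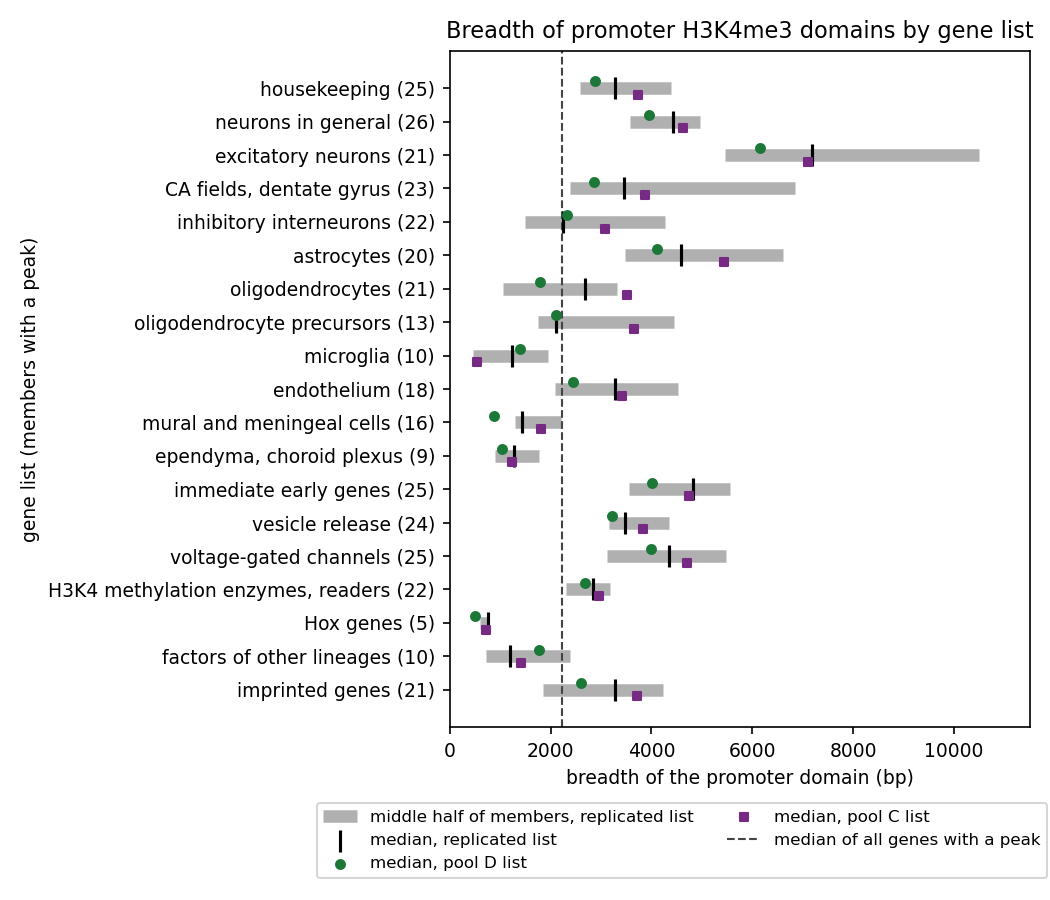
Breadth of the promoter domain in bp (x axis) for the marked members of each gene list (y axis, with their number). Black ticks are medians and grey bars the quartile range in the replicated list, circles and squares are medians in pool D and pool C, and the dashed line is the median of all marked genes (2234 bp). Excitatory neuron genes have the highest median, 7193 bp.

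Oligodendrocyte genes had wider domains in pool C than in pool D by more than other genes did, and several other lists did so under part of the matchings. Of the 19 genes marked in both pools 18 were wider in pool C, by a median of 1.29 on the log2 scale (2.44 times), against 0.23 for all genes. Draws of genes matched on pool C signal value had a median of 0.41 (0.23 to 0.70 in the middle 95%; permutation test, adjusted p = 0.00380 over 19 lists). The genes for myelin components Mobp (267 and 6450 bp in pool D and pool C), Mag (574 and 3544 bp) and Mbp (2425 and 7096 bp) and the transcription factor gene Olig2 (3520 and 8591 bp) showed it, while Gjc3 was narrower in pool C (1933 and 1356 bp). The precursor list, in which Sox8 and Olig2 had the broadest domains, had a median of 0.82 (12 genes; permutation test, adjusted p = 0.0665) and the microglia list 0.86 (6 genes; permutation test, adjusted p = 0.0745). The precursor list shares 3 of its 14 genes with other lists. Olig2 is also in the oligodendrocyte list, so these 2 lists are not independent. The astrocyte list had a median of 0.43 (20 genes; permutation test, adjusted p = 0.160) and the excitatory neuron list 0.25 (21 genes; permutation test, adjusted p = 0.905). The hippocampal field list, at 0.42 (22 genes), lay above its signal-matched draws (0.16 to 0.38). The voltage-gated channel list, at 0.12 (25 genes), lay below its own (0.14 to 0.31). Neither passed after adjustment (permutation test, adjusted p = 0.0665 for each). Against draws matched on breadth instead of signal value, more lists were wider in pool C. With matching on pool C breadth and on pool D breadth, the adjusted p of the permutation test was 0.00253 and 0.00190 for precursor genes, 0.00912 and 0.0180 for microglia genes, and 0.00190 and 0.00443 for mural and meningeal genes (median 0.82, 15 genes). It was 0.0260 and 0.00253 for endothelial genes (median 0.60, 15 genes) and 0.0271 and 0.0168 for interneuron genes (median 0.48, 19 genes; permutation test). Astrocyte and hippocampal field genes passed with matching on pool D breadth alone (permutation test, adjusted p = 0.00443 and 0.00285), and voltage-gated channel genes lay below draws matched on pool C breadth (median 0.12, permutation test, adjusted p = 0.00912). These breadth ratios were examined, and the oligodendrocyte genes named, after the values were seen, and each pool gave 1 peak list.

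**Figure D4:**
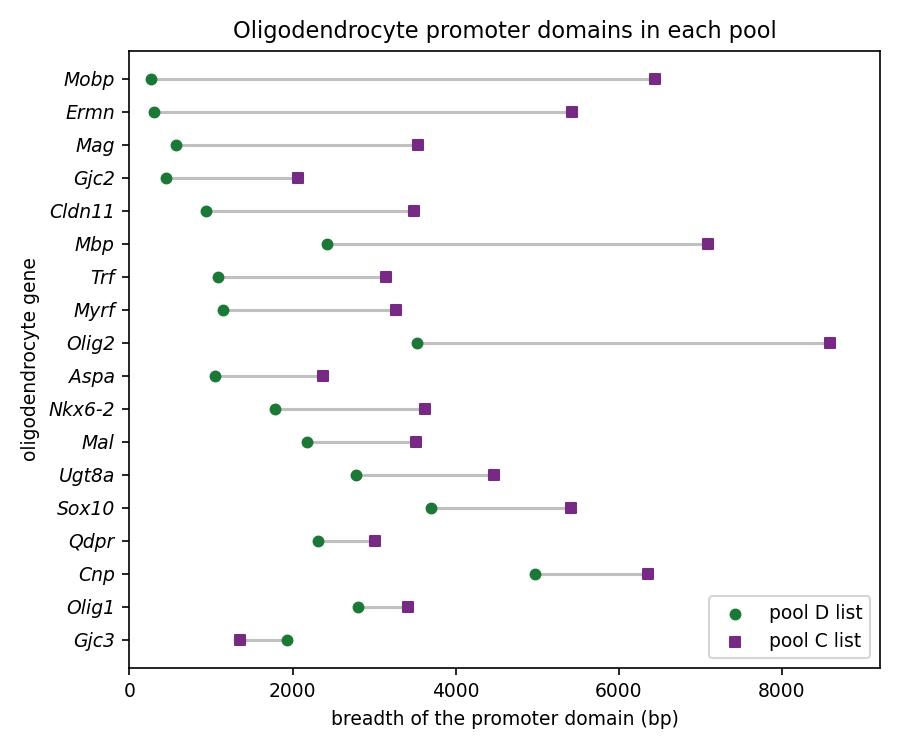
Breadth of the promoter domain in bp (x axis) of 18 of the 19 oligodendrocyte genes marked in both single-pool lists (y axis), with pool D as circles and pool C as squares joined by a line. All but Gjc3 are wider in pool C.

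Promoter domains found in a single pool were nearly all in pool C, with 818 there (median 510.5 bp) and 6 in pool D (at most 297 bp). The 5 broadest were at Slc32a1, the vesicular GABA transporter gene (3879 bp; chromosome 2, 158609586 to 158613464), Cyp2j12 (3682 bp; chromosome 4, 96137538 to 96141219), Slc22a8, an organic anion transporter gene (3132 bp; chromosome 19, 8591254 to 8594385), an alternative start site of Schip1 (2758 bp; chromosome 3, 68064089 to 68066846) and Ly6a (2561 bp; chromosome 15, 74995146 to 74997706). The strongest peaks over 10 kb from any start site were present in both pools. The first lay between genes on chromosome 12, 8640103 to 8641768, 33197 bp from the nearest start site of Pum2. The second was in an intron of the noncoding gene Lncppara on chromosome 15, 85670887 to 85677754. The others were intergenic, on chromosome 1 from 171101605 to 171103492, on chromosome 16 from 64872934 to 64874454 and on chromosome 2 from 32137327 to 32138024.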

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

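Of 890 values recomputed under the alternatives, 735 kept their direction and stayed on the same side of their threshold or within their limit. Among the values that answer a comparison this held for 61 of 64. Overlap between the whole pool lists, promoter share, genes with a promoter peak, the ratio of X to autosomes and the number of lists marked more or less often stayed within those limits under each alternative run. Within them, the promoter share ran from 47.6% in pool C alone to 66.2% at a −log10 q of at least 5. The share of pool C peaks found in pool D ran from 57.7% with reciprocal overlap of 50% to 86.9% with lists of equal length. The number of lists with broader domains was 10, and 6 with no gap closed between peaks. The number with narrower domains was 5, and 8 for covered bases within 5 kb. It ranged from 3 to 6 when either pool was left out, with 3 in pool D alone. The number of lists tested differs, since liver, muscle and lymphoid genes reached the minimum of 5 marked members for covered bases, and muscle genes and olfactory receptors did so in pool C, each then called narrower. Of the values for single genes, 112 of domain breadth moved beyond their limit and 343 did not, and 6 of 8 values for the lowest and highest signal deciles moved, most at the lowest decile of pool D (42.8% with reciprocal overlap of 50%). Some directions reversed. The oligodendrocyte share with a promoter peak was 61.9% at a −log10 q of at least 5 and the microglia share ranged from 24.0% in pool D alone to 76.0% in pool C alone. The median breadth of precursor genes ranged from 2102 bp in pool D alone to 3650 bp in pool C alone and was 4348 bp with gaps of 3 kb closed. With no gap closed it was 1461 bp for oligodendrocyte genes and 2025 bp for endothelial genes. The cause was not tested for these, except that fewer peaks enter at the stricter threshold and in pool D. A threshold of −log10 q of at least 2 was chosen after seeing the data. So were the settings for the oligodendrocyte difference between pools, whose median log2 ratio was 0.78 with no gap closed (signal-matched draws 0.23 to 0.70), 1.06 with gaps of 3 kb closed (0.21 to 0.71) and 1.01 for covered bases within 5 kb (0.28 to 0.71). The unadjusted permutation p was 0.0134, 0.0026 and 0.0008, against 0.0002 with gaps of 1 kb closed, so the excess was smallest with no gap closed. These p-values were not adjusted over the gene lists, unlike the adjusted p given for the main setting. Whether the excess would pass that adjustment in these settings was therefore not tested. Merging peaks within each list changed nothing, since no peaks of a list overlap. No paired analysis was possible because there is 1 condition and each pool gave 1 peak list. Depth is unknown, which limits what the absence of a weak peak in pool D shows.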

Other observations

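The widest single peak in the replicated list was not at a protein-coding gene. It spanned 27953 bp on chromosome 13, from 83714988 to 83742940, at the long noncoding gene C130071C03Rik, which hosts the neuronal microRNA gene Mir9-2. Its domain measured 29432 ± 707 bp over the pools (SD, n = 2). The other copies of that microRNA gene also lay in broad domains, Mir9-1 on chromosome 3 with 13716 ± 880 bp over the pools and Mir9-3 on chromosome 7 with 12289.5 ± 1565 bp. Host genes of another neuronal microRNA, Mir124a-1hg and Mir124-2hg, had domains of 7602 ± 774 and 6627.5 ± 859 bp over the pools. Long noncoding RNA genes with broad domains included Malat1 (9728 ± 231 bp), Neat1 (9639 ± 1184 bp) and Sox2ot, which measured 8914 bp in pool D and 20513 bp in pool C. Of 5854 long intergenic noncoding RNA genes 945 (16.1%) had a promoter peak, and of 9940 processed pseudogenes 179 (1.80%). Away from protein-coding promoters the shares were 585 of 5396 (10.8%) and 133 of 9730 (1.37%). These noncoding genes were chosen after their values were seen.

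The following tests were written before their results were seen, except those for the oligodendrocyte difference between pools and the separate tests of CpG content for other tissues, receptor genes and microglia genes. The design names no second group, so no biological explanation was tested apart from the cell content of the pools. The first pattern is the longer pool C list with its additional markers of rarer cells, and of the pool C peaks that pool D lacks, 99.8% lay below the median signal value of the pool C list, which is consistent with lower depth or weaker enrichment in pool D. Among genes unmarked in pool D, 24 of 61 markers of microglia, vessels, ependyma, oligodendrocytes and blood cells (39.3%) had a pool C peak against 548 of 7881 other genes (6.95%), an odds ratio of 8.67 (lower 95% bound 4.93; Fisher's exact p = 1.12e-12). However, 26.4% of the 91 markers with a pool C peak lacked one in pool D, within the 23.1% to 35.2% of genes matched on pool C signal value, so the loss of weak peaks whatever their gene would give this excess, and a difference in cell content cannot be told apart from it here. The oligodendrocyte difference in breadth, 1.29 on the log2 scale, lay above draws matched on pool C signal value (0.23 to 0.70), pool C breadth (0.16 to 0.44) or pool D breadth (0.18 to 0.46). Neither signal value nor breadth alone therefore gives it. Each matching used 1 measure, however, and these genes were broader than genes of like signal value (2691 bp against 717 to 1454 bp in the replicated list). Domains both weak and broad may be called narrower in pool D, which these draws cannot exclude. A larger share of oligodendrocytes in pool C may account for the oligodendrocyte difference. Only 2 of 21 oligodendrocyte genes were missed in pool D, below the 3 to 8 of signal-matched genes. A narrow remnant counts as marked, however, as at Mobp (267 bp in pool D and 6450 bp in pool C). The count of missed genes therefore cannot decide on a difference in oligodendrocyte share. Other lists were wider in pool C too. Precursor (0.82 against 0.19 to 0.68), microglia (0.86 against 0.12 to 0.74) and hippocampal field genes (0.42 against 0.16 to 0.38) lay above signal-matched draws before adjustment. Voltage-gated channel genes lay below theirs (0.12 against 0.14 to 0.31). Precursor, microglia, endothelial, mural and interneuron genes lay above breadth-matched draws, so a broader difference between the pools stays open as well.

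The second pattern is the breadth of promoter domains in the lists called broader, with a median of 3994 bp over 225 genes against 2234 bp for all marked genes. CpG count at the gene's 5′ end does not account for it, since draws matched on that count had a median of 2205 bp (2041 to 2376) and 101.6% of the excess was left. Some domains lay away from the 5′ end, as at Ywhaz and Egfl7, whose 5′ ends held 11 and 12 CpG dinucleotides. The CpG content of the marked promoter itself was therefore not tested. Several start sites per gene do not account for the breadth either, with matched draws at 2270 bp (2107 to 2456) and 98.0% left. Nor do stronger peaks, with draws matched on signal value at 2145 bp (1983 to 2325) and 105.1% left. A biological origin, such as long domains at genes that define the main cells of the tissue, may hold as a hypothesis, found on these data and not tested. The 225 genes also include housekeeping, imprinted and endothelial genes. Other causes, such as allelic differences of the hybrid animals against the reference genome, stay open.

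The third pattern is the missing mark at Hox genes and factors of other lineages, and at 1607 genes of other tissues, receptors and microglia, where the planned test left 12.9% of the deficit, between the bounds set beforehand, and was then split by group. A low CpG count at the 5′ end does not account for Hox genes and factors of other lineages. Of these 69 genes 21.7% were marked against 85.5% (78.3% to 91.3%) of genes matched on that count, so that 147.9% of the deficit was left. Over 119 genes of liver, muscle, germ, blood and skin cells 10.1% were marked against 38.3% (31.1% to 46.2%) of matched genes, with 51.5% of the deficit left, and CpG content is not the whole cause there, although liver genes alone reached the lower bound of their matched draws (8.33%). For 1463 olfactory and vomeronasal receptor genes, 0.205% were marked against 6.88% (5.67% to 8.20%) of matched genes, so 10.3% of the deficit was left beyond CpG content. In the replicated list microglia genes were marked as often as genes of like CpG content (40.0% against 38.5%, 24.0% to 56.0%; −6.01% of the deficit left). The same genes were marked at 24.0% in pool D alone and at 76.0% in pool C alone, where they did not differ from other genes. CpG content is the same in both pools, so it does not give the difference between them. Of 19 microglia genes marked in pool C, 13 were missed in pool D, within the 9 to 14 of signal-matched genes. Genes matched on CpG count were not drawn within either pool. Whether CpG content alone accounts for the deficit in the replicated list therefore stays open.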
